A study of Mus musculus with 3 samples.

How the data were processed

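Gene expression was measured in 1 droplet library of pooled, hashtagged mouse T cells sorted from B16F10 tumors. Libraries of hashtags and of T cell receptors from the same pool were not analysed here. The deposited gene table holds raw counts of UMIs per gene and cell, with 14811 genes and 5564 cells. A deposited antibody table holds raw counts for 138 antibodies, 4315 counts in all. A deposited annotation gives each cell a number from 1 to 4, a Cd4 or Cd8 identity and a class of Cd4, Cd8 or Tdp. Cell Ranger 3.1.0, Seurat 3.2.3 and the mm10 genome build are named in the submitters' processing notes, with no role or order. How the authors filtered cells, removed doublets, assigned hashtags or called the classes is not given in the sources used here. Tested on the files, all 406 Tdp cells had a UMI of both Cd4 and Cd8a, 8 other cells had both, no cell exceeded 4.99% mitochondrial UMIs, and the lowest total was 501 UMIs. About 6200 cells were loaded, per the labels' protocols.

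The planned comparisons were between sorted populations. The labels list these populations in different orders, and nothing ties a number to a population, so the comparisons used the authors' classes instead. The numbers served for shares of cells within a number, for matching single-class cells to Tdp cells, and for ratios within a number, the last given where both classes had at least 20 cells. Because the Tdp class needs a UMI of both genes, deeper cells enter it more easily. The single classes also hold cells with no co-receptor UMI.

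Counts were summed over the cells of a class and given as CPM over all genes except 117 T cell receptor and immunoglobulin genes, which hold 0.325% of the UMIs. Log2 ratios used a pseudocount of 5 CPM and folds used none. Intervals are exact Poisson for levels, exact conditional binomial for ratios and exact (Clopper-Pearson) binomial for shares of cells, all at 95% and for counting error only. Library totals per class were 10733467 UMIs for the Cd4 class, 574490 for Cd4-identity Tdp, 13567317 for the Cd8 class and 1887857 for Cd8-identity Tdp, so the Cd4-identity Tdp values are the least precise.

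Before the data were examined, 15 gene lists, 19 marker lists and the rules for naming genes were fixed. A member counted as measured with at least 20 UMIs over both classes. The median of a list was set beside 10000 random lists of the same size and matched expression, and its interval came from 2000 Poisson draws. Named genes were the 12 highest and 12 lowest log2 ratios among genes with at least 20 CPM in the higher class, 100 UMIs, a UMI in 5% of its cells and an interval that leaves out 1, plus Cd4, Cd8a, Cd8b1, Zbtb7b and Runx3 and the 2 highest and 2 lowest members of each list. Receptor, mitochondrial, ribosomal and unnamed genes were left out. The rule covers 82, 76, 78 and 74 genes in the 4 comparisons, of which the text names a part, and some genes and 1 antibody that these rules select are not reported here. Fewer than 3 members were measured in any comparison for gamma delta T cell, B cell, neutrophil, fibroblast, endothelial and erythroid markers. Melanoma markers, of which 3 or 4 were measured in 3 comparisons, had medians of -0.44, -0.53 and -0.058.

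Cells were clustered with scanpy 1.11.5 and igraph 0.11.9 on 2000 variable genes without receptor, mitochondrial and ribosomal genes, with 20 principal components, 15 neighbours and Leiden resolution 0.5. Shared-neighbour edge weights were tried first and, after those clusters were seen, replaced by the default weights, with the former kept as an alternative. Scrublet marked 0 of 5564 cells as doublets and was taken not to have worked. Cells with at least 2 UMIs of each of 2 or more Trbv genes (T cell receptor beta V genes) were used as a sign of doublets instead. For shares at equal depth, cells were thinned to 2000 UMIs, which kept 5143 cells, namely 2245 of the Cd4 class, 89 of Cd4-identity Tdp, 2500 of the Cd8 class and 309 of Cd8-identity Tdp.

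The ratio step was tested on simulated Poisson counts with 2-fold changes, in genes with at least 100 UMIs expected over both classes. A gene was found when its interval left out 1 in the right direction. The 1.5-fold rule was not applied, so these rates are not those of the list member calls. For Cd8-identity Tdp against the Cd8 class the ratio step found 99.0% of raised and 86.0% of lowered genes among 8631, for Cd4-identity Tdp against the Cd4 class 84.0% and 55.0% among 7924, for the Tdp classes 99.0% and 96.0% among 3554, and for the single classes 100% and 99.0% among 9348. Alternatives were the mean of per-cell CPM, a cell filter, thinned cells, pseudocounts of 1 and 20 CPM, other UMI minimums, TMM scaling (edgeR 4.0.16), and leaving out cycling cells, cells with the other co-receptor, Foxp3 cells or cells with UMIs of other cell types. The last were cells with at least 2 UMIs of macrophage or monocyte, B cell or melanoma markers. Leaving them out kept 1817 cells of the Cd4 class, 57 of Cd4-identity Tdp, 1665 of the Cd8 class and 164 of Cd8-identity Tdp. It thus also removed cells of the T cell clusters. Chosen after seeing the data were the matched single-class cells, the T cell clusters, the cells with UMIs of 2 Trbv genes, the lists without Cd4 and Cd8a, and 2 further clusterings. Also set after seeing results were which lists are treated as answering a comparison (the CD4 and CD8 lineage lists), and that a gene's change of sign is counted only where it passed the 1.5-fold rule. Not run were the alternatives that need hashtag counts or clonotypes, and the clonotype comparison. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.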

Results

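The data came from 1 pool of T cells sorted from B16F10 melanoma, a transplantable mouse melanoma line, taken from the tumors of 10 pooled mice. Purified CD4 T cells carrying the congenic marker CD45.1, or CD8 T cells carrying CD45.2, were injected 1 day after the tumor cells, and tumors were resected on day 11. Cells with CD4 alone, CD8 alone, or both co-receptors from either origin were sorted, given a hashtag each and loaded as about 6200 cells on a droplet device that reads the 5′ end of transcripts. Hashtag and T cell receptor libraries were also made and are not analysed here. The table of counts held 5564 cells, 14811 genes and 26763131 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule). The median cell had 3869 UMIs from 1585 genes, with 1.17% mitochondrial UMIs. The design addresses how double-positive T cells of CD4 and of CD8 origin relate to the single-positive cells of their own origin and to each other.

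The comparisons used the authors' classes per cell. The authors gave each cell a Cd4 or a Cd8 identity, and called 406 cells Tdp. How the identity was called is not given in the sources used here. It may rest on lineage transcripts of these same cells, so lineage differences between the identities may follow from the label. Each Tdp cell held at least 1 UMI of both Cd4 and Cd8a, the genes of the co-receptors CD4 and CD8 alpha, so these genes set the class and their levels in it are no finding. Of the Tdp cells, 313 had a Cd8 identity and 93 a Cd4 identity. The remaining cells formed a Cd8 class of 2681 and a Cd4 class of 2477. Tdp cells were 4.51%, 8.41%, 4.47% and 12.4% of all cells in hashtag samples 1 to 4. Cells sorted as double-positive had hashtags of their own, so most of them must lie in the Cd8 and Cd4 classes. Tdp therefore does not stand for the sorted double-positive cells, and identity is not shown to be origin. The median number of UMIs per cell was 4981 in Cd8-identity Tdp, 4159 in the Cd8 class, 4668 in Cd4-identity Tdp and 3478 in the Cd4 class. The 4 hashtag samples carry only numbers, which the labels do not tie to a sorted population, so no value is given by sorted population. Those samples are parts of 1 pool and not replicates, so a direction kept across them is not replication. Each class comes from 1 pool in 1 library, so there was no test across samples, and every interval is a 95% interval that covers counting error only. A list member is called higher or lower when it differed by at least 1.5-fold with an interval that leaves out 1, which is a rule of size. A list stands apart when its median lies outside the central 95% of 10000 random lists of matched expression, and lists were rerun under up to 17 alternatives.

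Tdp cells made up 10.5% of Cd8-identity cells (313 of 2994, exact binomial interval 9.38 to 11.6) and 3.62% of Cd4-identity cells (93 of 2570, 2.93 to 4.41). Among Cd8-identity cells the share was 10.8% in hashtag sample 1, 11.5% in sample 2, 4.52% in sample 3 and 16.5% in sample 4. Among Cd4-identity cells it was 2.15%, 4.79%, 4.27% and 5.20%. Both identities occurred under every hashtag number, with a Cd8 identity in 27.2%, 54.3%, 81.1% and 63.7% of the cells of samples 1 to 4. Cells with UMIs of both Cd4 and Cd8a were 10.6% of Cd8-identity and 3.74% of Cd4-identity cells. With at least 2 UMIs of each gene these shares were 2.94% and 0.661%, and after thinning each cell to 2000 UMIs they were 3.77% and 1.24%. In the Cd8 class Cd4 was found in 2.65% of cells, a share held down by the class rule, since nearly all cells with both UMIs were called Tdp. Cd8b1, the CD8 beta chain that does not set the Tdp class, was found in 11.7% of the Cd4 class, 57.0% of Cd4-identity Tdp, 85.0% of the Cd8 class and 89.8% of Cd8-identity Tdp.

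**Figure D1:**
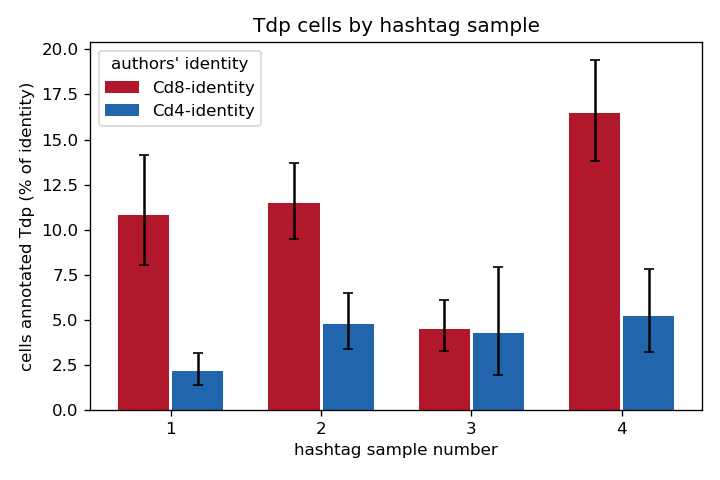
Share of cells annotated Tdp (y axis, percent of the cells of an identity) in each hashtag sample (x axis, sample number), for Cd8-identity and Cd4-identity cells, with exact 95% binomial intervals as error bars (counting error only). The Cd8-identity share runs from 4.52% in sample 3 to 16.5% in sample 4.

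Clustering gave 10 clusters. Cluster 1 was led by Ccl5 and Cd8b1, cluster 2 by Serpinb1a, Il17re and Cd40lg, and cluster 3 was regulatory T cell-like, led by Foxp3, Tnfrsf9 and Il2ra. Cluster 4 was cycling-like (Ccna2, Birc5). Cluster 5 was led by Lyz2 and the MHC class II genes H2-Aa and H2-Eb1, genes of macrophages and dendritic cells. Cluster 6 was led by Igfbp4, cluster 7 by interferon-induced genes such as Ifit3 and Rsad2, cluster 9 by Csf2 and Ccl4, and cluster 10 was NK-like (Ncr1, Klrb1c). Cluster 8, with a median of 899 UMIs, was left unnamed. In a clustering made without Cd4, Cd8a and Cd8b1, the cycling cluster held 18.8% of Cd8-identity Tdp (14.7 to 23.6) and 12.5% of the Cd8 class (11.3 to 13.8). Cells of that cluster were deep (median 8198 UMIs), and among Cd8 class cells matched on hashtag sample, UMI total and a Cd8a UMI, a choice made after seeing the data, its share was 21.1% (18.0 to 24.5). The cluster led by Igfbp4 held 1.60% of Cd8-identity Tdp (0.521 to 3.69), 7.39% of the Cd8 class (6.42 to 8.44) and 7.51% of the matched cells. The cluster led by Ccl5 and Cd8b1 held 9.68% of Cd4-identity Tdp (4.52 to 17.6) and 3.51% of the Cd4 class (2.82 to 4.31). In the first clustering, a rule set after the clusters were seen kept some clusters apart from the T cell clusters. These were the clusters led by myeloid or NK genes and cluster 8, the latter for its low UMI total alone. They held 13.7% of the Cd8 class, 6.39% of Cd8-identity Tdp, 5.05% of the Cd4 class and 3.23% of Cd4-identity Tdp.

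The first comparison asked how Cd8-identity Tdp cells differ from the Cd8 class. Beside Cd4 (26.5-fold higher, 21.6 to 32.6), the genes higher in Tdp cells included Ccr9, a chemokine receptor of gut homing (4.61-fold, 3.46 to 6.11, in 3 of 4 hashtag samples, with a log2 ratio of 1.76 that was 1.13 without cells holding UMIs of other cell types), and genes of cell division. Ccr9 was found in 23 Tdp cells, and 37 of its 84 UMIs lay in 2 cells with at least 3 other genes of plasmacytoid dendritic cells. Without such cells in either class Ccr9 was 3.00-fold higher (2.09 to 4.25). Prc1, which acts in cytokinesis, was 1.94-fold higher (1.65 to 2.27), Bub1b of the spindle checkpoint 2.01-fold (1.52 to 2.62), Cdc20 1.87-fold (1.56 to 2.24) and Arhgap19 2.78-fold (1.93 to 3.94). Without cycling cells the log2 ratios of Prc1, Cdc20 and Arhgap19 were 0.44, 0.081 and 0.25 (from 0.89, 0.84 and 1.09). Ccr7, a chemokine receptor of lymph node homing, was 1.68-fold lower (1.32 to 2.16). The chemokine receptor gene Cxcr6 was 1.57-fold higher (1.46 to 1.68) and Rgs1 1.56-fold higher (1.36 to 1.78), both in 4 of 4 hashtag samples. Gzmk, a granzyme gene, was 1.51-fold higher (1.38 to 1.64).

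Of 10 naive and memory genes 3 were lower and none higher in Cd8-identity Tdp cells, with a median log2 ratio of -0.33 (-0.44 to -0.21), below all 10000 random lists of matched expression. The medians were -0.19, -0.32, -0.28 and -0.26 in hashtag samples 1 to 4. Of 9 CD8 lineage genes only Xcl1 was called, at 3.81-fold lower (2.84 to 5.23), and the list median was -0.27 (percentile 0). That list did not hold its direction within hashtag samples, where its medians were 0.37, -0.42, -0.35 and -0.093. Cd8b1 was 1.11-fold lower (1.07 to 1.16) and Runx3, a transcription factor of the CD8 lineage, 1.02-fold higher (0.905 to 1.14). The CD4 lineage and helper list, which includes Cd4, had a median of 0.18 (percentile 93.5, and 0.13 without Cd4), with -0.17, 0.29, 0.36 and -0.094 in the samples. That median was 0.45 against matched Cd8 class cells, 0.020 with each cell counting the same and 0.022 without cells holding UMIs of other cell types. Zbtb7b, which encodes the CD4 lineage factor ThPOK, stood at 16.5 CPM (11.2 to 23.4) in Tdp cells and 15.3 CPM (13.3 to 17.5) in the Cd8 class.

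Proliferation genes had a median of 0.39 (0.25 to 0.46), with 3 of 14 higher, Ube2c 1.64-fold (1.51 to 1.79) and Ccna2 1.53-fold (1.34 to 1.75). Hashtag sample 1 went the other way, with medians of -0.36, 0.90, 0.31 and 0.31 in samples 1 to 4. Against the matched Cd8 class cells that median was -0.17. Without cycling cells it was 0.076, with log2 ratios of -0.19 for Bub1b and -0.0054 for Ube2c. Among the T cell receptor activation genes 3 of 12 were lower, Nr4a1 2.09-fold (1.43 to 3.15), with a list median of -0.31 (-0.43 to -0.12; -0.74, -0.20, -0.60 and -0.052 in the samples) that became 0.0080 against matched cells. The tissue residency median of 0.29, with 3 of 8 higher, was -0.29, 0.32, 0.40 and 0.20 in the samples, and became -0.050 when each cell counted the same. Smaller medians lay below the central 95% of random lists for type I interferon response (-0.098, 2 of 11 lower), Th1 and effector cytokines (-0.090, 2 of 13 higher and 4 lower) and inhibitory receptors (-0.090, none of 12 called). The intervals of the cytokines (-0.29 to 0.071) and the inhibitory receptors (-0.17 to 0.037) include 0, and none of these lists kept 1 direction across the hashtag samples. These lists no longer stood apart in 4, 4 and 7 of the 17 alternatives, with medians of -0.054, -0.071 and -0.011 without cycling cells. Cytotoxic (0.027), Th2, Th17 and Tfh (-0.10), regulatory T cell (-0.085), glycolysis (0.087), thymocyte (0.080) and dissociation stress (-0.073) lay within it. Of the lists within it, the CD4 lineage and helper list included, 4 stood apart against matched Cd8 class cells and 2 with matched cells in T cell clusters. Foxp3 was 2.17-fold higher (1.54 to 3.02) and was found in 4.47% of Tdp cells against 2.91% of the Cd8 class. Its log2 ratio was -0.43 without cells holding UMIs of other cell types. That setting kept 164 Cd8-identity Tdp and 1665 Cd8 class cells, and also removed cells of the T cell clusters.

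Markers of other cell types moved with this comparison. All 10 macrophage or monocyte markers were lower in Cd8-identity Tdp cells (median -1.15, -1.29 to -1.03), and all 6 NK markers were lower (median -0.85). Of 7 dendritic cell markers 5 were lower and 1 was higher (median -0.79). The most strongly lower genes were of this kind: Plbd1 was 7.45-fold lower (4.90 to 11.9), H2-Eb1 4.23-fold (3.75 to 4.78), H2-Aa 3.99-fold (3.61 to 4.41) and Cd74 2.95-fold (2.81 to 3.1). Within T cell clusters H2-Eb1, H2-Aa and Cd74 changed sign, with log2 ratios of 0.54, 0.42 and 0.73.

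The next comparison asked the same of Cd4-identity Tdp cells and the Cd4 class. Besides Cd8a, the Tdp cells held 7.0-fold more Cd8b1 (6.16 to 7.95), at 587 CPM (526 to 653) against 83.8 CPM (78.4 to 89.5). Also higher were Cd160, a receptor of cytotoxic lymphocytes, at 4.12-fold (2.68 to 6.16), Prf1, which encodes perforin, at 3.42-fold (2.12 to 5.32), Cd7 at 2.77-fold (2.28 to 3.34), the chemokine gene Ccl5 at 2.37-fold (2.27 to 2.48) and the NK receptor gene Klrd1 at 2.34-fold (1.82 to 2.97), each in 3 of 3 hashtag samples with at least 20 Tdp cells. Pdcd1, which encodes the inhibitory receptor PD-1, was 1.84-fold higher (1.52 to 2.22). Lower were Il2ra, the interleukin-2 receptor alpha chain, at 2.28-fold (1.61 to 3.35), Ccr8 at 2.26-fold (1.25 to 4.56), Zbtb7b at 1.83-fold (1.11 to 3.22) and Tnfrsf4, which encodes OX40, at 1.75-fold (1.51 to 2.04). The chemokine genes Ccl3 and Ccl4 stood 5.99-fold (5.0 to 7.15) and 5.07-fold (4.51 to 5.69) higher in the sum, but in only 1 of 3 hashtag samples, and Ccl3 was found in 5.38% of the cells.

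Of 9 CD8 lineage genes 4 were higher and 1 was lower in Cd4-identity Tdp cells, with a median of 0.74 (0.23 to 1.17), above all random lists. Cd8a, which sets the class, is 1 of the 4, and without it the median was 0.55, still above all random lists. The median was 0.97, 0.28 and 0.23 in hashtag samples 1, 2 and 4. Without cells that held UMIs of 2 T cell receptor beta V genes it was 0.13 (percentile 80.7). In that setting Cd8b1, Cd160 and Prf1 still had log2 ratios of 2.40, 2.20 and 1.34. Such cells, counted among cells with at least 4 Trbv UMIs, were 47.4% of Cd4-identity Tdp (36 of 76, 35.8 to 59.2) and 20.8% of matched Cd4 class cells (14.2 to 28.8). Of 7 CD4 lineage and helper genes, Cd4 included, 3 were lower (median -0.36, percentile 0.070, and -0.55 without Cd4), with 0.091, -0.73 and -0.34 in the samples. This call was lost in 5 of 17 alternatives, among them leaving out cells with UMIs of other cell types (-0.078). Of 14 regulatory T cell genes 5 were lower (median -0.44, -0.67 to -0.34), while Foxp3 was found in 19.4% of Tdp cells and 22.4% of the Cd4 class. Of 11 cytotoxic genes 3 were higher and 1 lower (median 0.45), and with matched cells in T cell clusters the median was -0.20 (percentile 1.43).

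Type I interferon response genes had a median of -0.31 (2 of 11 lower), with Oasl2 1.73-fold lower (1.17 to 2.69) and Rsad2 1.69-fold lower (1.14 to 2.60). That list no longer stood apart with matched cells in T cell clusters (-0.15). Glycolysis (-0.14, 1 of 11 lower) and dissociation stress (-0.24, 2 of 12 lower) also lay below the central 95% of random lists, but no longer in 5 and 4 of the 17 alternatives. Without cells holding UMIs of other cell types their medians were -0.018 and -0.10, and in hashtag sample 2 they were 0.084 and 0.031. Th1 and effector cytokines (0.052), Th2, Th17 and Tfh (0.024), inhibitory receptors (-0.053), naive and memory (0.12), T cell receptor activation (0.041), tissue residency (0.033), proliferation (0.061) and thymocyte genes (0.19) lay within it. Of these lists 4 stood apart against matched Cd4 class cells, and 3 with matched cells in T cell clusters. Of 10 macrophage or monocyte markers 9 were lower (median -1.83), as were Cd74 at 4.67-fold (3.96 to 5.56) and H2-Ab1 at 6.53-fold (4.30 to 10.4). Of 4 measured dendritic cell markers 3 were lower and none higher (median -2.36). Within T cell clusters H2-Ab1 had a log2 ratio of 0.59.

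**Figure D2:**
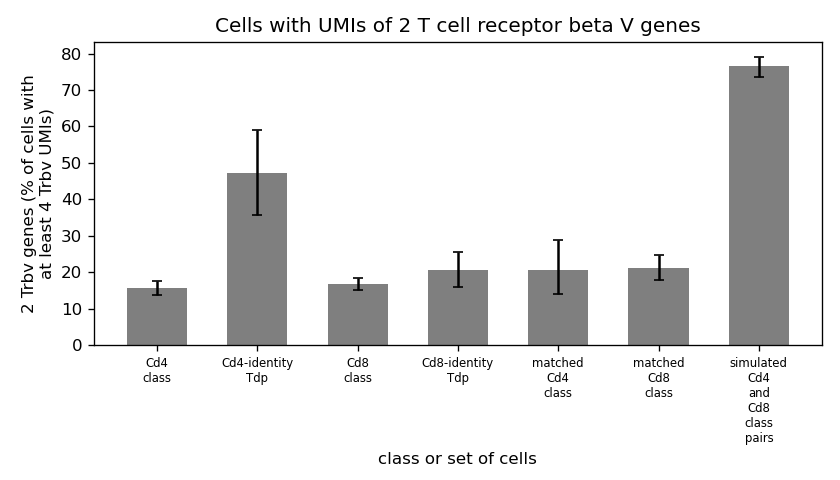
Percent of cells with at least 2 UMIs of each of 2 or more T cell receptor beta V genes (y axis), among cells with at least 4 UMIs of these genes, in the 4 classes, in matched single-class cells and in simulated pairs of a Cd4 and a Cd8 class cell (x axis), with exact 95% binomial intervals as error bars (counting error only). Cd4-identity Tdp stood at 47.4%, Cd8-identity Tdp at 20.5% and the simulated pairs at 76.5%. The pairs are whole cells added without thinning and are not matched in depth to the Tdp cells.

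**Figure D3:**
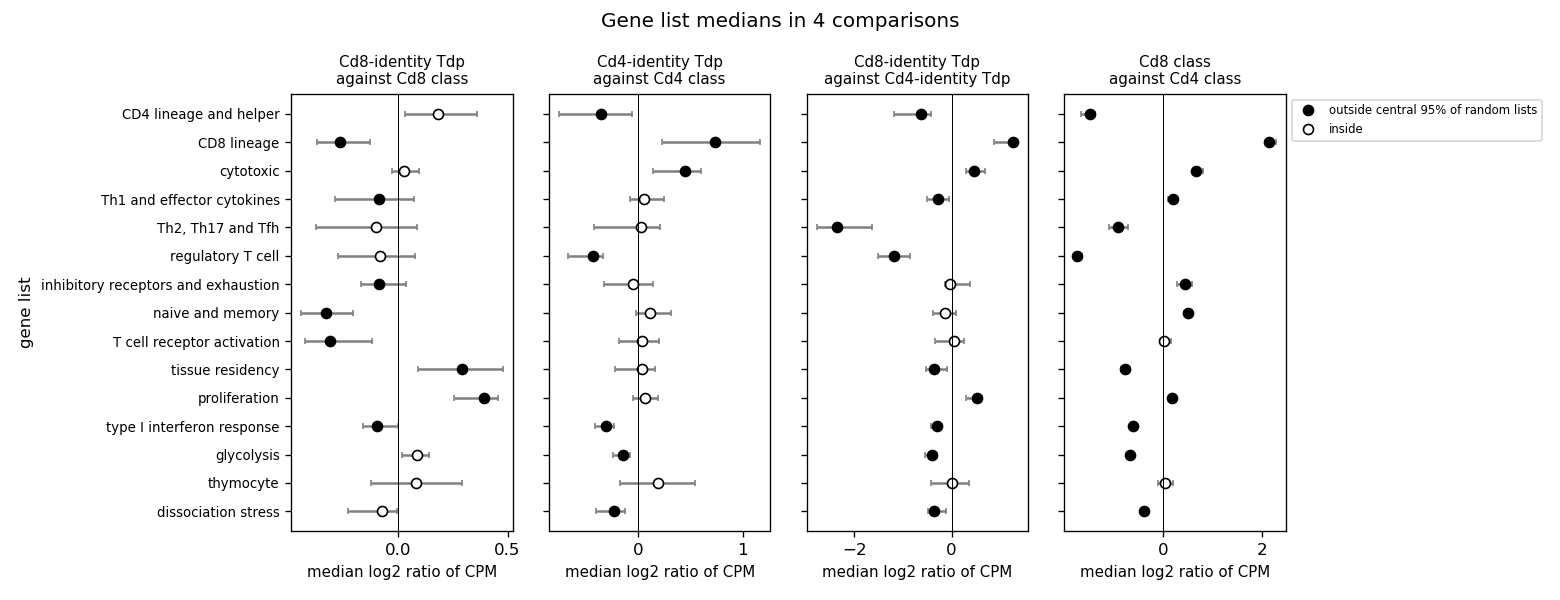
Median log2 ratio of CPM (x axis, log2 scale) of each gene list (y axis) in the 4 comparisons, with 95% intervals from Poisson draws of the counts (error bars, counting error only) and filled points outside the central 95% of 10000 random lists of matched expression. The CD8 lineage median runs from -0.27 for Cd8-identity Tdp against the Cd8 class to 2.14 for the Cd8 class against the Cd4 class.

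The Tdp cells of both identities were then compared with each other. Cd8-identity Tdp cells had more of the granzyme gene Gzmk (3.27-fold, 2.52 to 4.31), Eomes, a transcription factor of effector and memory CD8 cells (3.91-fold, 1.71 to 11.0), Dapl1 (2.84-fold, 1.66 to 5.21) and Cd8b1 (2.36-fold, 2.10 to 2.65). Cd4-identity Tdp cells had more Foxp3, the regulatory T cell factor (4.72-fold, 3.22 to 6.98), Cd40lg, a helper ligand (3.78-fold, 2.57 to 5.57), Ctla4 (2.88-fold, 2.20 to 3.77), Maf (2.77-fold, 2.04 to 3.77), Icos (2.19-fold, 1.77 to 2.70) and Itgae, an integrin of tissue-resident cells (4.26-fold, 2.51 to 7.32). Each of these 10 genes kept its direction in 3 of 3 hashtag samples. Zbtb7b was 1.70-fold lower in Cd8-identity Tdp cells with an interval (0.866 to 3.2) that includes 1, and Runx3 was 1.27-fold higher (0.991 to 1.63).

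In this comparison 8 of 9 CD8 lineage genes were higher in Cd8-identity Tdp cells (median 1.26, 0.87 to 1.36; 1.04, 1.62 and 1.23 in samples 1, 2 and 4). Of the CD4 lineage and helper genes 3 of 7 were lower (median -0.62; -1.04, -0.63 and -0.89), and of the regulatory T cell genes 9 of 11 were lower (median -1.17). Among the 3 measured Th2, Th17 and Tfh genes, Ccr6 (15.1-fold, 5.62 to 50.9) and Ccr4 (8.09-fold, 4.13 to 16.8) were lower and Sh2d1a was 1.59-fold higher (1.26 to 2.01). Cytotoxic genes had a median of 0.46 (4 of 10 higher, 1 lower), and Gzmb was the lower one at 1.60-fold (1.41 to 1.83), in 1 of 3 hashtag samples. Proliferation had a median of 0.52 (5 of 14 higher), which was 0.068 without cycling cells. Glycolysis (-0.40), dissociation stress (-0.36), tissue residency (-0.35), type I interferon response (-0.30) and Th1 and effector cytokines (-0.27) lay below the central 95% of random lists. Tissue residency no longer did in 3 of the 17 alternatives (-0.12 without cells holding UMIs of other cell types) and Th1 and effector cytokines in 2 (-0.098 in thinned cells). Interferon response (-0.15) and dissociation stress (-0.081) no longer did without cells with UMIs of 2 Trbv genes. Some of the 17 alternatives, such as the matched single-class cells, change only single-class cells and cannot alter a comparison of the Tdp classes. By hashtag sample, glycolysis (0.19) and dissociation stress (0.14) were above 0 in sample 1 and Th1 and effector cytokines (0.35) in sample 4. Inhibitory receptors (-0.031), naive and memory (-0.13), T cell receptor activation (0.054) and thymocyte genes (0.017) lay within it. Of 6 measured macrophage or monocyte markers 5 were higher (median 2.29), and Fcer1g was 6.54-fold higher (3.84 to 12.1). Of 5 measured dendritic cell markers 3 were higher and none lower (median 1.86).

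The Cd8 and Cd4 classes gave the scale of the lineage difference. The Cd8 class had 18.3-fold more Cd8b1 (17.1 to 19.6), 26.4-fold more Dapl1 (20.3 to 34.9), 12-fold more Eomes (8.90 to 16.6), 12.6-fold more Crtam (8.82 to 18.6) and 4.93-fold more Ccl5 (4.85 to 5.01). The Cd4 class had 30.0-fold more Cd4 (25.0 to 36.2), 13.2-fold more Foxp3 (11.2 to 15.7), 6.59-fold more Cd40lg (5.89 to 7.38), 6.81-fold more Tnfrsf4 (6.37 to 7.27), 3.33-fold more Zbtb7b (2.84 to 3.93) and 31.1-fold more Il17re (16.6 to 65.7). Runx3 was 1.44-fold higher in the Cd8 class (1.35 to 1.54). All of these genes kept their direction in 4 of 4 hashtag samples. The Cd4 fold is no measure of the lineage difference. Of 414 cells with UMIs of both Cd4 and Cd8a, 406 were placed in Tdp, which takes Cd4 out of the Cd8 class.

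In the Cd8 class 8 of 9 CD8 lineage genes were higher (median 2.14; 2.09, 2.87, 1.90 and 2.06 in samples 1 to 4) and 6 of 7 CD4 lineage and helper genes lower (median -1.46; -1.17, -1.70, -1.66 and -1.46). Regulatory T cell genes were lower in 13 of 14 (median -1.73) and Th2, Th17 and Tfh genes in 9 of 13 with 2 higher (median -0.91). Cytotoxic genes were higher in 7 of 11 (median 0.67), including Prf1 at 4.18-fold (3.46 to 5.08), while Gzmb was 1.82-fold lower (1.76 to 1.89), or 0.11 on the log2 scale in the other direction without cells holding Foxp3. Glycolysis genes were lower in 8 of 11 (median -0.66; Aldoa 1.92-fold, 1.87 to 1.96), type I interferon genes in 7 of 11 (median -0.61) and tissue residency genes in 5 of 8 (median -0.76; Rgs1 3.03-fold, 2.83 to 3.24). Naive and memory genes had a median of 0.51 with 3 of 10 higher, among them Ccr7 at 3.66-fold (3.13 to 4.31). Inhibitory receptors had a median of 0.44, which was -0.24 with each class replaced by cells matched to its own Tdp cells. Th1 and effector cytokines had a median of 0.20, which was -0.56 with such matched cells in T cell clusters. The matched Cd8 and Cd4 class cells (median 5038.5 and 4676 UMIs before the limit to T cell clusters) were not matched to each other. The cytokine median was -0.22, 0.17, -0.094 and 0.19 in samples 1 to 4 and no longer stood apart in 2 further alternatives, and the inhibitory receptor median was -0.013 in sample 1. Proliferation (0.17, no longer apart in 2 alternatives, among them 0.050 without Foxp3 cells) and dissociation stress (-0.38) lay outside the central 95% of random lists, and T cell receptor activation (0.018) and thymocyte genes (0.043) within it. All 10 macrophage or monocyte markers (median 1.22), all 7 dendritic cell markers (median 1.22) and all 6 NK markers (median 0.88) were higher in the Cd8 class.

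The place of the Tdp cells between the classes was read over 186 genes at least 2-fold apart between the Cd8 and Cd4 classes, chosen on a random part of the cells. Ratios to the rest of the Cd4 class were divided by the class difference in the part that chose the genes. Cd4-identity Tdp cells lay 25.1% (20.1 to 28.4) of the way from the Cd4 to the Cd8 class at the median gene, and Cd8-identity Tdp cells 78.1% (75.0 to 81.2). The held-out cells of the Cd8 class lay at 92.6%, so this and not the full way is the Cd8 end of the scale. The shortfall shows the bias of choosing genes by size, and the intervals leave out the error of the class difference. Without Cd4, Cd8a and Cd8b1 the positions were 25.1% and 78.0%. Cells with UMIs of 2 Trbv genes, 47.4% of Cd4-identity Tdp cells and 20.8% of matched Cd4 class cells with at least 4 Trbv UMIs, were kept in. Doublets may therefore add to the position of Cd4-identity Tdp cells.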

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

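The tests of doublets and free RNA for Cd4-identity Tdp, of free RNA for Cd8-identity Tdp and of plasmacytoid dendritic cells were chosen after the result was seen, as was the choice of antibodies named here.

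The antibody table is outside the comparisons above, and 85 antibodies other than CD4 and CD8a gave counts above the upper limit of the highest of 3 isotype controls (3 counts, upper limit 8.77). Some of the antibodies that differed at least 2-fold between the single classes, or gave 0 counts in 1 of them, with an interval that leaves out 1, are given by total over all cells, with counts in the Cd8 and Cd4 classes in parentheses: Ly-6C 47 (31 and 12), CD11b 24 (18 and 4), CD5 202 (56 and 138), I-A/I-E 63 (42 and 16), Ly-6A/E 91 (26 and 61), CD45.2 34 (23 and 7), GITR 65 (7 and 50), CD103 13 (0 and 13), Fc-RI 35 (23 and 7), SLAM 95 (29 and 58), P-selectin 11 (10 and 1), DAF 39 (11 and 26), Galectin-3 41 (26 and 11), CD61 42 (13 and 26), TCR V-2.1 72 (22 and 48), XCR1 11 (9 and 0) and CXCR5 9 (9 and 0). The antibody named TCR V-5.1, 5.2 gave 17 (13 and 0). CD45.1, the marker of the injected CD4 T cells, missed the 2-fold rule with 108 counts (38 and 65). The CD45.2 counts are therefore not read as a sign of origin. CD4 gave 86 counts in the Cd4 class and 5 in the Cd8 class, and CD8a 3 and 74. Names are as the table gives them, and no difference was tested across samples. The counts cover whole classes, and 13.7% of the Cd8 class and 5.05% of the Cd4 class lay outside the T cell clusters. The antibody differences are therefore not shown to be differences between T cells.

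Cd4-identity Tdp cells held more CD8 lineage transcripts than the Cd4 class. Cd8b1 was found in 57.0% of them (46.3 to 67.2) and in 11.3% of matched Cd4 class cells, which cannot decide on free RNA. Tdp cells were selected for a Cd8a UMI and nearly all matched cells lack one, so free RNA holding both genes would also raise Cd8b1. Depth is argued against, since the list median without Cd8a was still 0.57 (0.11 to 0.88) against matched cells. Doublets stay open: among cells with at least 4 Trbv UMIs, 47.4% of Tdp cells held 2 Trbv genes against 20.8% of matched cells and 76.5% of simulated pairs. The pairs were a whole Cd4 and a whole Cd8 class cell added without thinning. They were not matched to the depth of Tdp cells, so their share gives no scale for the share of doublets. Without cells holding 2 Trbv genes the list median was 0.13. In the remaining 57 cells Cd8b1 (2.40 from 2.74), Cd160 (2.20 from 1.70), Prf1 (1.34 from 1.44), Ccl5 (1.56 from 1.24) and Klrd1 (1.06 from 1.16) stayed higher, genes picked after their values were seen, and doublets with only 1 Trbv gene detected may remain among them. A co-receptor change in CD4 T cells, the biological explanation the design names, was not tested and stays open.

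Cd8-identity Tdp cells held Cd4 transcripts. Doublets with a CD4 T cell as the whole cause are argued against, since 12 genes of the Cd4 class had a median log2 ratio of 0.62 (0.46 to 0.93) against matched cells where an equal mixture would give 1.95, and since 20.5% of those with at least 4 Trbv UMIs held 2 Trbv genes (16.1 to 25.6) against 21.1% of matched cells. The mixture is an assumed profile, so a smaller share of doublets may remain. Free RNA alone is only weakly argued against, since after thinning Cd4 was found in 1.91% of Cd8-identity cells of the cluster led by Igfbp4 (0.524 to 4.83) and in 7.89% of those of the largest cluster (6.64 to 9.30). The first clustering was used, which did not leave out Cd4, so a Cd4 UMI could itself affect where a cell was placed. The lower share rests on 4 of 209 cells. Cd4 expression in CD8 T cells, which the design names, stays open and untested.

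Siglech and Ccr9, which plasmacytoid dendritic cells express, were higher in Cd8-identity Tdp cells than in the Cd8 class (27.1 against 3.55 CPM and 44.7 against 9.69 CPM). Of the 6 other genes of the list 5 also had more CPM in Tdp cells, Tcf4 (21.3 against 13.2), Klk1 (7.44 against 1.70), Cox6a2 (14.4 against 3.85), Ly6d (10.6 against 5.77) and Cd300c (1.60 against 0.444), and Pacsin1 had less (16.0 against 19.2). For Ccr9, such cells, alone or in doublets with T cells, are argued against as the whole source, since without cells holding at least 3 of those 6 genes, in either class, 47 of its 84 UMIs remained, in 21 cells, and it was 3.00-fold higher (2.09 to 4.25). For Siglech they are a candidate source, since 100% of its 51 UMIs lay in 3 cells that held at least 3 of those 6 genes. Whether these 3 were such cells alone or doublets stays open, since all 3 held Cd3e, but so did 312 of 313 cells of the class and 42.7% of the Cd8 class cells of the cluster led by Lyz2, and no biological explanation was tested.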

How the results depend on the processing

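The settings with matched cells, T cell clusters and cells with UMIs of 2 Trbv genes, the lists without Cd4 and Cd8a, and 2 clusterings were chosen after the results were seen. Over the settings run for each (17 for 57 list medians and 16 for 3, which had too few members at a minimum of 100 UMIs), list medians gave 817 values that stayed within their interval, 189 that moved and 11 that changed sign, named genes 3315, 966 and 59, and cluster shares 138, 22 and 0. Of list calls, 607 were kept, 51 were lost, 4 turned and 46 were gained. These totals include settings that cannot change a result. Leaving out Cd4 and Cd8a changes only lists that hold them. Between the Tdp classes, matching single-class cells or leaving out those with the other co-receptor changes nothing. There the matched setting in T cell clusters repeats the plain one. Given here are the values of lineage lists that moved and of any called list or gene that changed sign; the choice of the lineage lists as the answer to each comparison, and of the 1.5-fold rule for a change of sign, came after results were seen. The cause was not tested for any of them unless the setting removes the cells that carry the genes. With 93 cells, Cd4-identity Tdp had the lowest UMI total of the 4 classes (574490). Hashtag and clonotype settings were not run. No paired analysis was possible because no comparison comes from a test: there is 1 pool without biological replicates, and ratios within hashtag samples are values only.

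With each cell counting the same, log2 values for Cd8-identity Tdp against the Cd8 class were CD4 lineage and helper list 0.020 (from 0.18) and tissue residency list -0.050 (from 0.29). Between the Tdp classes they were CD8 lineage list 1.48 (from 1.26). Between the single classes they were CD8 lineage list 2.56 (from 2.14).

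In thinned cells, log2 values for Cd8-identity Tdp against the Cd8 class were Il12rb2 -0.028 (from 0.70). In the Cd8 against the Cd4 class they were CD8 lineage list 2.44 (from 2.14).

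At a pseudocount of 1 CPM, log2 values between the single classes were CD4 lineage and helper list -1.67 (from -1.46).

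At a pseudocount of 20 CPM, log2 values between the Tdp classes were CD8 lineage list 0.86 (from 1.26). The Cd8 and Cd4 classes gave CD4 lineage and helper list -1.32 (from -1.46) and CD8 lineage list 1.62 (from 2.14).

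Without cycling cells, log2 values for Cd8-identity Tdp against the Cd8 class were tissue residency list -0.098 (from 0.29), Bub1b -0.19 (from 0.85), Depdc1a -0.047 (from 0.78) and Ube2c -0.0054 (from 0.70). Between the Tdp classes they were CD8 lineage list 1.41 (from 1.26), Hist1h4d -0.11 (from 1.43) and Hist1h1b -0.57 (from 1.36). Between the single classes they were CD8 lineage list 2.72 (from 2.14).

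Without single-class cells holding the other co-receptor, log2 values between the single classes were CD8 lineage list 2.28 (from 2.14) and Th1 and effector cytokines list -0.12 (from 0.20).

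Without Foxp3 cells, log2 values for Cd4-identity Tdp against the Cd4 class were Tnfrsf9 0.21 (from -0.65). In the Cd8 against the Cd4 class they were CD8 lineage list 2.01 (from 2.14), Gzmb 0.11 (from -0.86) and Itgae 0.48 (from -1.09).

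Without cells holding UMIs of other cell types, log2 values for Cd8-identity Tdp against the Cd8 class were CD4 lineage and helper list 0.022 (from 0.18), Foxp3 -0.43 (from 0.87), Cd74 0.35 (from -1.56), Lgmn 0.037 (from -1.64), H2-Ab1 1.47 (from -1.91), H2-Aa 0.60 (from -1.97) and H2-Eb1 0.78 (from -2.04). For Cd4-identity Tdp against the Cd4 class they were Ms4a6c 0.39 (from -1.28), Sdc4 0.017 (from -1.63), Cd74 0.62 (from -2.20) and H2-Ab1 0.46 (from -2.56). Between the Tdp classes they were Cd74 -1.63 (from 1.86). The Cd8 and Cd4 classes gave CD4 lineage and helper list -1.82 (from -1.46) and CD8 lineage list 2.63 (from 2.14).

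Against matched single-class cells, log2 values for Cd8-identity Tdp against the Cd8 class were CD4 lineage and helper list 0.45 (from 0.18), CD8 lineage list -0.41 (from -0.27), T cell receptor activation list 0.0080 (from -0.31), proliferation list -0.17 (from 0.39), type I interferon response list 0.14 (from -0.098), Atf3 0.90 (from -0.63), Ebi3 0.12 (from -0.83), Wfdc17 0.45 (from -1.63), Lgmn 0.26 (from -1.64) and Ccl6 0.88 (from -1.78). Between the single classes, each replaced by cells matched to its own Tdp class and not to the other single class, they were CD4 lineage and helper list -1.69 (from -1.46), CD8 lineage list 2.53 (from 2.14), inhibitory receptor list -0.24 (from 0.44), Csf2 -0.59 (from 1.16), Atf3 -0.63 (from 1.13) and Egr2 -0.48 (from 0.64).

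In T cell clusters, log2 values for Cd8-identity Tdp against the Cd8 class were Cd74 0.73 (from -1.56), Wfdc17 0.12 (from -1.63), Lgmn 0.18 (from -1.64), Cst3 0.094 (from -1.81), H2-Ab1 0.80 (from -1.91), H2-Aa 0.42 (from -1.97) and H2-Eb1 0.54 (from -2.04). For Cd4-identity Tdp against the Cd4 class they were Ms4a6c 0.041 (from -1.28) and H2-Ab1 0.59 (from -2.56). Between the Tdp classes they were H2-Aa -0.28 (from 2.00), H2-Ab1 -0.67 (from 2.00) and Cd74 -0.88 (from 1.86). In the Cd8 against the Cd4 class they were CD4 lineage and helper list -1.89 (from -1.46), CD8 lineage list 2.38 (from 2.14) and Irf8 -0.28 (from 0.87).

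With matched cells in T cell clusters, log2 values for Cd8-identity Tdp against the Cd8 class were proliferation list -0.030 (from 0.39), type I interferon response list 0.022 (from -0.098), Ebi3 0.060 (from -0.83), Cd74 0.76 (from -1.56), Wfdc17 0.18 (from -1.63), Lgmn 0.13 (from -1.64), Cst3 0.16 (from -1.81), H2-Ab1 0.69 (from -1.91), H2-Aa 0.55 (from -1.97), H2-Eb1 0.79 (from -2.04) and Plbd1 0.077 (from -2.46). For Cd4-identity Tdp against the Cd4 class they were cytotoxic list -0.20 (from 0.45), Xcl1 0.25 (from -1.28) and H2-Ab1 0.38 (from -2.56). Between the Tdp classes they were H2-Aa -0.28 (from 2.00), H2-Ab1 -0.67 (from 2.00) and Cd74 -0.88 (from 1.86). The Cd8 and Cd4 classes, each matched to its own Tdp class, gave CD4 lineage and helper list -1.96 (from -1.46), CD8 lineage list 2.31 (from 2.14), Th1 and effector cytokines list -0.56 (from 0.20), Csf2 -0.56 (from 1.16), Irf8 -0.49 (from 0.87) and Egr2 -0.10 (from 0.64).

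Without cells with UMIs of 2 Trbv genes, log2 values for Cd4-identity Tdp against the Cd4 class were CD8 lineage list 0.13 (from 0.74) and Ccr7 -0.95 (from 0.75). Between the Tdp classes they were CD8 lineage list 1.81 (from 1.26).

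The positions of Cd4-identity and Cd8-identity Tdp were 30.4% and 82.0% over genes 4-fold apart (from 25.1% and 78.1%), and 29.5% and 83.2% at a pseudocount of 20 CPM. Cells with both Cd4 and Cd8a were 2.94% of Cd8-identity cells (from 10.6%) and 0.661% of Cd4-identity cells (from 3.74%) at 2 UMIs of each, and 3.77% and 1.24% after thinning.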

Other observations

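No test in this part was chosen before the results were seen. In the clustering without Cd4, Cd8a and Cd8b1, the cluster led by Il17re, Serpinb1a and Cd40lg held 6.71% of Cd8-identity Tdp (4.20 to 10.1) and 2.09% of the Cd8 class (1.58 to 2.70). Of the Cd8-identity cells in that cluster 27.3% were Tdp (21 of 77, 17.7 to 38.6), against 10.8% in the cluster led by Ccl5 and Cd8b1 (9.39 to 12.4). Among matched Cd8 class cells the cluster led by Il17re held 1.12% (0.451 to 2.29). It held 41.9% of Cd4-identity Tdp (31.8 to 52.6), 53.7% of the Cd4 class (51.7 to 55.7) and 44.6% of matched Cd4 class cells (37.3 to 52.1). The Foxp3-led cluster held 25.8% of Cd4-identity Tdp (17.3 to 35.9), 23.7% of the Cd4 class (22 to 25.4) and 20.4% of matched Cd4 class cells (14.9 to 26.9).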
